A study of Homo sapiens with 10 samples.

How the data were processed

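Total RNA from 94T778 cells, an established human liposarcoma line that the labels describe as well differentiated, was sequenced in 10 libraries. Untreated parental cells had 4 libraries. Cells kept under nutlin-3a at 2.5 µM for 10 weeks, under palbociclib at 7 µM for 10 weeks or under tunicamycin at 0.14 µM until 9 weeks after a population bottleneck had 2 libraries each. RNA was extracted with a column kit, per the labels' protocols. The library kit, the strand setting and the gene annotation were not given in the sources used here.

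The authors deposited 1 table of raw counts per gene for each library. HISAT2 2.04, HTSeq 0.6.1 and limma 3.34.9 and the genome builds hg19 and GRCh37 are named per the submitters' processing notes, without a role or an order. Each table held whole numbers for 50775 gene symbols, of which 31720 had a count in at least 1 library, and closing lines for reads that were not assigned to a gene. Those lines stayed out of library sizes and tests. As percentages of all reads of a library, they covered 7.32 to 9.67% in no annotated gene, 1.63 to 2.12% fitting more than 1 gene, 2.35 to 2.68% of low alignment quality, 0.277 to 0.335% not aligned and 13.4 to 16.6% not aligned uniquely. Reads with several alignments were therefore not in the gene counts, and levels of near-identical genes (histones, ribosomal proteins, the MAGE and PAGE families, globins, keratins and HLA genes) are uncertain. Without a stated strand, reads from a gene and an antisense or overlapping partner cannot be told apart. Symbols are given as in the tables. Some are older names, such as KIAA1530 for UVSSA, MEIR5 for SFR1, C9orf119 for SWI5, C9orf142 for PAXX, C17orf70 for FAAP100, CCDC111 for PRIMPOL and SC5DL for SC5D. The reference annotation at hand was of another build (GENCODE 29 on GRCh38). It gave 13309 of the tested genes a gene type and a neighbour order, and no coordinates are printed. The values of some single genes are not reported here, and counts of named genes and of outlying values leave them out.

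Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 16526, libraries were scaled with TMM factors, and 1 quasi-likelihood model with a mean per group was fitted to all 10 libraries (glmQLFit and glmQLFTest). Each drug was compared with parental, the mean of the 3 drugs with parental, and each drug with each other drug, 7 comparisons in all. The test was two-sided with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Every adjusted p of a single gene is from this test unless another tool is named. Levels are CPM with TMM factors, fold changes are fitted values, SE is the standard error of the log2 fold change, and SD is the spread between libraries. Where every library of a group was at 0, the fold was computed against a floor of 3 counts per library, 0.157 CPM in the smallest library after scaling, and is a lower bound. Where a group held 1 to 3 counts in all, the ratio of counts is given with its 95% exact interval.

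Groups, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The 34 lists covered 9 DNA repair groups, the cell cycle, drug targets and stress responses, metabolism, secreted and matrix proteins, markers of other cell types and signs of RNA quality. The union of the 9 repair lists held 157 tested genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 34 lists, and a list is said to be called where this test passed. The same test with the correlation estimated from the residuals and fry were alternatives. Fry tests each list without comparing it with other genes. Named genes were 11 fixed genes, the 6 highest and 6 lowest changes of each drug among called genes with a mean of at least 5 CPM and no overlap between the groups, up to 4 members of each described list by adjusted p, and 12 repair genes changed alike under all 3 drugs. For the mean and the drug pairs they were the 4 highest and 4 lowest. The rule for the highest and lowest left out clone names, pseudogenes, mitochondrial genes, XIST and Y-linked genes.

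Alternatives were RLE, upper quartile and no scaling factors, no filter or a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, a minimum absolute log2 fold change of 1, leaving out each library in turn, and the date in the title as a block. Both libraries of each drug shared the same pair of title dates, 3 January for replicate 1 and 4 February for replicate 2, and 1 parental library carried the February date. The other 3 parental libraries each had a date of their own. The labels do not say what the date marks. Differences between the January and February libraries correlated across genes at r = -0.17 between nutlin-3a and palbociclib, 0.30 between nutlin-3a and tunicamycin and -0.25 between palbociclib and tunicamycin. The block left 2 residual degrees of freedom and let only the February parental library inform a drug's difference from parental. A further 4 alternatives were chosen after seeing the data. They included limma-voom with 1 weight per group and the block with the palbociclib dates exchanged. The others were repair genes outside a cell cycle list and the medians of the chromosome runs in each drug library.

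Protein-coding genes with a mean log2 CPM above 3 were ordered along chromosomes, 9230 in all, and the median log2 fold change was taken in sliding windows of 41 genes. Runs were stretches of at least 20 genes beyond the most extreme median of 100 shuffled orders, joined over gaps of up to 10 genes. This scan was chosen after seeing the data. Intervals of list medians are 95% bootstrap intervals from 2000 draws of the genes, and they cover the spread between genes, not between libraries.

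The test was tested on simulated counts with seeded changes, drawn for about as many genes as were tested. For nutlin-3a, 26.6% of the 1.5-fold, 69.2% of the 2-fold and 88.9% of the 4-fold changes were recovered over 15939 genes, with 5 false calls. For palbociclib the shares were 27.7%, 70.1% and 93.8% over 15941 genes, with 10 false calls. For tunicamycin they were 16.9%, 73.4% and 92.3% over 15949 genes, with 7. These simulations changed few genes and gave drug and parental libraries the same spread, unlike the data, so the shares may not carry over. A list lowered in a nutlin-3a simulation of 15954 genes was called and 0 of the others were. The run search found 1 run for 60 seeded neighbours among 9230 genes, with 32 of them inside and 0 genes from outside.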

Results

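Gene counts were compared between 10 RNA sequencing libraries of 94T778, an established cell line from a human well-differentiated liposarcoma, a fat-lineage tumour in which the genomic region of MDM2 and CDK4 is amplified. The series was made to ask how anti-cancer drugs with defined targets affect the expression of DNA repair genes. Parental cells without drug had 4 libraries. Nutlin-3a, which blocks the binding of MDM2 to p53, palbociclib, which inhibits the cell cycle kinases CDK4 and CDK6, and tunicamycin, which blocks the DPAGT1 step of N-linked glycosylation, had 2 libraries each. Libraries held 18814114 to 25246596 counts in genes, and fibronectin (FN1) took the largest share in each, 2.46 to 4.29%. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Intervals of count ratios and floors cover counting error only.

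Libraries of 1 group resembled each other more than libraries of different groups. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.992 to 0.995 between parental libraries, 0.988 for nutlin-3a, 0.982 for palbociclib and 0.985 for tunicamycin, against 0.886 to 0.952 between groups. The chi-square per degree of freedom between replicate libraries was 2.77 to 8.35 in parental and 28.4, 36.1 and 42.7 in the 3 drugs, so drug replicates differed more than parental ones. Mitochondrially encoded genes took 1.80 ± 0.229% of counts in parental (SD, n = 4), 3.29 and 3.39% in the nutlin-3a libraries, 3.86 ± 0.166% under palbociclib and 2.20 ± 0.199% under tunicamycin (n = 2 each). Ribosomal protein genes took 3.57 ± 0.144%, 2.22 ± 0.225%, 3.00 ± 0.194% and 4.69 ± 0.629% in the same order.

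The comparison of nutlin-3a with parental asked which genes, and which repair genes, differed after long exposure to an MDM2 inhibitor. Targets of p53 were higher as a list, a call that was lost with an estimated correlation (adjusted p = 0.364). CDKN1A, which encodes the CDK inhibitor p21, rose 9.76-fold, from 62.7 ± 4.71 CPM (SD, n = 4) to 612 ± 24.0 CPM (n = 2), a log2 fold change of 3.29 ± 0.093 (SE, adjusted p = 1.42e-08). MDM2, a p53 target that encodes its ubiquitin ligase, rose 2.71-fold, from 5338 ± 517 to 14480 ± 3480 CPM (log2 fold change 1.44 ± 0.15, adjusted p = 2.5e-05).

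**Figure D1:**
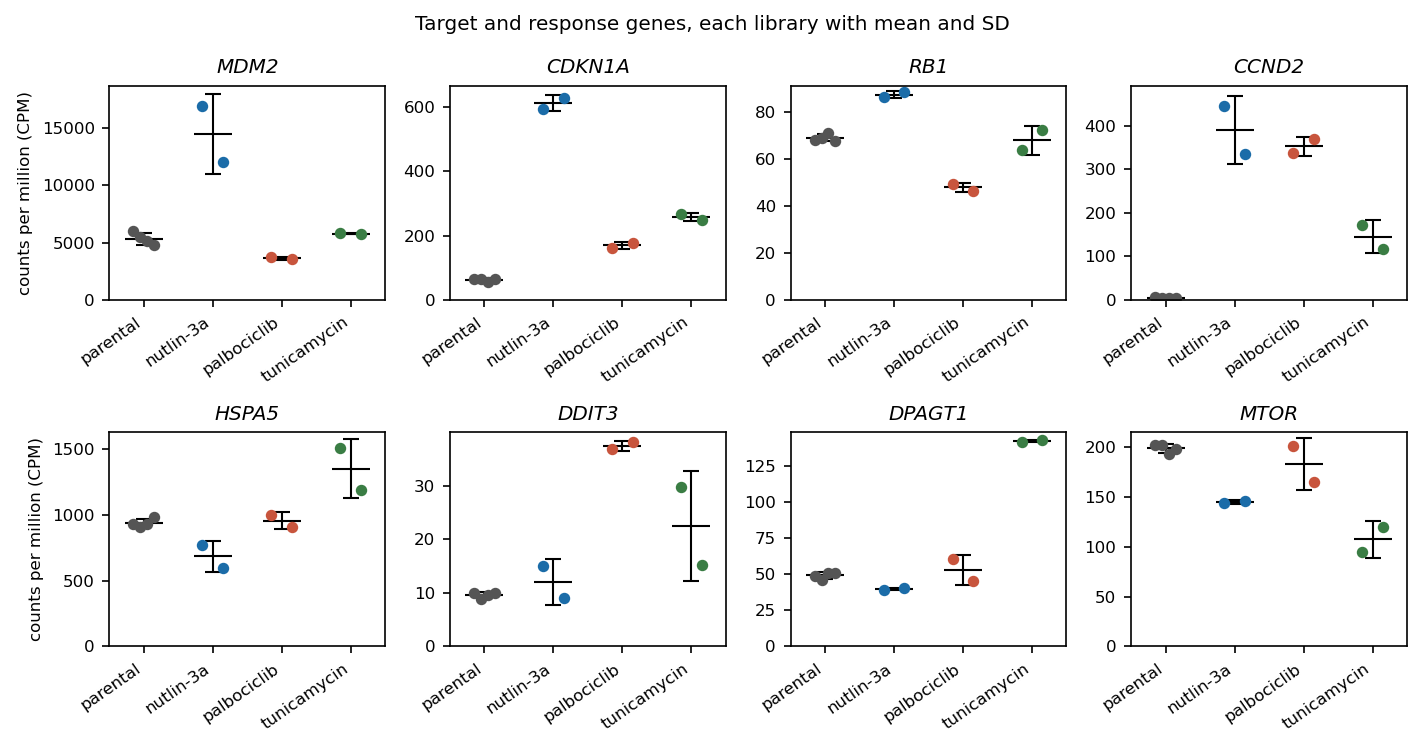
CPM of 8 genes in each library, 1 panel per gene with its own axis from 0, with the groups along the horizontal axis. Points are libraries and black bars the mean and SD; CDKN1A stood at 62.7 CPM in parental and at 612, 169 and 258 CPM under nutlin-3a, palbociclib and tunicamycin.

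Of 34 p53 target genes, 28 rose and 1 fell under nutlin-3a (29 and 1 adjusted over the list alone), with a median log2 fold change of 1.11. The list was called higher at adjusted p = 2.01e-18, and adjusted p = 0.364 with an estimated correlation. Besides CDKN1A, SPATA18, EDA2R and ZMAT3 rose, with log2 fold changes of 5.19, 2.00 and 1.57. The sestrin genes SESN1, SESN2 and SESN3, whose products restrain mTOR complex 1, rose 2.82-fold, 2.14-fold and 29.1-fold, within a list of mTOR regulators that was not called (13 higher, 11 lower of 37, adjusted p = 0.707). MTOR fell 1.37-fold (adjusted p = 0.00575). For this and every later list, the count adjusted over the list alone equalled that over all genes unless it is given. No list called against parental turned direction with RLE factors or with library totals, and the drug pairs were not tested so.

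DNA repair genes were mostly lower under nutlin-3a. Of 157 tested, 16 rose and 99 fell (17 and 102 adjusted over the list alone), the median log2 fold change was -0.52, and 63.1% fell against 27.3% of other genes. Homologous recombination (1 higher and 26 lower of 33 genes, 1 and 27 adjusted over the list alone), the Fanconi anaemia pathway (1 and 15 of 17) and base excision repair (1 and 13 of 23) were called lower, as were replicative polymerases (1 and 12 of 14) and the damage checkpoint (1 and 13 of 19). Their adjusted p values were 1.69e-05, 0.00148, 0.00249, 0.00066 and 0.00148, and each had adjusted p = 0.506 with an estimated correlation. In replicates 1 and 2 the list medians were -1.01 and -0.624 for homologous recombination, -0.987 and -0.575 for Fanconi anaemia and -1.18 and -0.741 for replicative polymerases. They lay closer for base excision repair (-0.658 and -0.501) and the checkpoint (-0.663 and -0.578). RAD54B and XRCC3, which act in strand exchange, changed by -1.77 and -1.28, BRIP1, a BRCA1-associated helicase, by -1.55 ± 0.25 (SE), and APEX1, the main abasic site endonuclease, by -0.77. The catalytic polymerase subunits POLE and POLD1 fell 2.64-fold and 2.57-fold, and the checkpoint mediator MDC1 fell 2.02-fold.

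Other repair groups held members that moved both ways under nutlin-3a. In end joining, PRKDC, the DNA-dependent protein kinase, fell 3.12-fold and XRCC6 (Ku70) fell 1.94-fold, while LIG4 rose 1.71-fold and APLF 2.52-fold (2 higher and 6 lower of 14 genes, adjusted p = 0.256). In nucleotide excision repair, ERCC2 and ERCC1 changed by -1.11 and -0.89 and KIAA1530 (UVSSA), which acts in transcription-coupled repair, by 0.90 (5 higher and 9 lower of 24, adjusted p = 0.201). Low-fidelity polymerases had 3 higher, among them POLH at 0.79 and POLN at 1.37, and 2 lower of 12 (adjusted p = 0.995). Mismatch repair had 1 higher and 7 lower of 9 (2 and 7 adjusted over the list alone, adjusted p = 0.126), with EXO1 at -1.78 and MLH3 at 0.58. Camera called none of these 4 lists, while fry called end joining, nucleotide excision repair and mismatch repair lower (adjusted p = 0.00201, 0.00268 and 0.0131). Calls by fry alone were not particular to repair. N-linked glycosylation and the 12q13-15 amplicon were also called lower, and efflux genes higher, by fry only (adjusted p = 0.0324, 0.00917 and 0.00161).

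Cell division genes were lower under nutlin-3a. All 33 tested G2/M genes fell, with a median of -1.54, for example the anaphase activator CDC20 (4.72-fold, from 404 to 85.5 ± 42.3 CPM) and the spindle gene ASPM (3.43-fold). Of 27 replication licensing genes 26 fell and 0 rose, with RPA1 at -1.18 ± 0.085 and MCM4 at -1.62 ± 0.21. Both lists were called (adjusted p = 5.35e-09 and 1.28e-08, each with adjusted p = 0.506 with an estimated correlation). The libraries stood apart, with list medians of -2.23 and -1.09 for G2/M, -2 and -1.04 for licensing and -1.09 and -0.48 for nucleotide supply in replicates 1 and 2. Nucleotide supply had 1 higher, the p53-inducible reductase subunit RRM2B (3.37-fold), and 8 lower of 12, at adjusted p = 0.0499. That call was lost with an estimated correlation (adjusted p = 0.559), with RLE factors (adjusted p = 0.0527) and with the date block (adjusted p = 0.0717). In the E2F and RB list, 5 rose and 12 fell of 23 (adjusted p = 0.496), and the cyclin gene CCND2 rose 78.4-fold, from 4.95 ± 1.01 to 390 ± 77.7 CPM.

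Metabolic lists changed as well under nutlin-3a. Glycolysis and hypoxia genes fell (0 higher and 23 lower of 29), for example the glucose transporter SLC2A1 (2.13-fold) and VEGFA (2.73-fold), and so did cholesterol synthesis (1 and 16 of 23), with ACAT2 at -1.99, and both lists had adjusted p = 0.506 with an estimated correlation. Lysosome and autophagy genes rose (19 higher, 0 lower of 30, 19 and 1 adjusted over the list alone), among them LAMP1 and LAMP2 (1.73-fold and 2.22-fold). The lists had adjusted p values of 5.98e-08, 4.58e-05 and 0.00066, each with adjusted p = 0.506 with an estimated correlation. Ribosomal protein genes fell (0 higher, 70 lower of 76) and mitochondrially encoded genes rose (11 higher, 0 lower of 12, and 12 adjusted over the list alone) at adjusted p = 1.01e-19 and 4.69e-05, each with adjusted p = 0.506 with an estimated correlation.

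Interferon-stimulated genes (19 higher and 1 lower of 32, 20 and 1 adjusted over the list alone) and secreted inflammatory factors (12 and 3 of 24, 13 and 3) rose under nutlin-3a. Adjusted p values were 0.00148 and 0.0177, each with adjusted p = 0.559 with an estimated correlation, and the second was 0.059 with library totals. List medians in replicates 1 and 2 were 0.98 and 0.50 for the interferon list and 1.43 and 0.47 for the inflammatory one. OAS1, which makes the activator of RNase L, and the peptide transporter TAP1 rose 7.42-fold and 3.08-fold, and the adhesion receptor ICAM1 and the binding protein IGFBP7 rose 4.60-fold, to 131 ± 68.5 CPM with its libraries far apart, and 26.0-fold. Matrix genes had 10 higher and 10 lower of 31 (adjusted p = 0.71), with thrombospondin THBS1 2.77-fold lower and tenascin TNC 3.13-fold higher. Adipocyte genes had 4 and 8 of 17 (adjusted p = 0.297), with the fatty acid enzymes FASN and SCD 2.96-fold and 9.93-fold lower, and efflux and xenobiotic genes 13 and 5 of 23 (adjusted p = 0.164), with CYP1B1 19.2-fold higher. ER chaperones had 9 and 14 of 27 (adjusted p = 0.45), N-linked glycosylation 4 and 11 of 33 (adjusted p = 0.158), the 12q13-15 amplicon 6 and 15 of 26 (adjusted p = 0.094) and histones 12 and 6 of 25 (adjusted p = 0.183). The ATF4 list had 6 and 8 of 25 (7 and 8 adjusted over the list alone, adjusted p = 0.297), with a median of 0.093, a mean of -0.028 and a test direction of lower, and ATF4 itself fell 2.11-fold.

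The largest single changes under nutlin-3a included PLCH2, a phospholipase C gene, at 139 ± 14.7 CPM against 0.0485 ± 0.0429 in parental. SCUBE1 and TP53I11 had no count in any parental library and were at least 72.1-fold and 43.3-fold higher. PPP2R2C, CPXM2 and EYA2 had 1 to 3 parental counts, and the ratios were 1010 (95% interval 280 to 8360), 2630 (472 to 104000) and 1100 (197 to 43400). LHX1, a homeobox gene, had no count under nutlin-3a and was at least 38.0-fold lower, and ANPEP, an aminopeptidase, fell 48.0-fold from 496 ± 72.4 to 10.3 ± 3.38 CPM. KRT81, SV2A and PAGE1 fell 51.2-fold, 40.5-fold and 51.9-fold, and MAGEA12 had a ratio of 114 (31.5 to 939) between parental and drug.

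In all, 9276 of 16526 genes changed under nutlin-3a, 4710 higher and 4566 lower. With library totals as the scale, 64.1% of calls were higher against 50.8%, the median of all genes stood at 0.17 against 0.018, and repair genes had a median of -0.36. The date block left 957 genes and 4 repair genes, and without nutlin-3a replicate 1 the changed repair genes numbered 76 instead of 115.

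The comparison of palbociclib with parental asked the same of long exposure to a CDK4 and CDK6 inhibitor. Cell cycle and DNA replication genes were lower, and genes of the integrated stress response were higher, as list calls that were lost with an estimated correlation (adjusted p = 0.328 for each of licensing, G2/M and the ATF4 list). KIF20A, a mitotic kinesin, fell 9.86-fold, from 230 ± 10.9 CPM (SD, n = 4) to 23.3 ± 12.4 CPM (n = 2, adjusted p = 4.74e-05). SLC7A11, the cystine transporter induced by ATF4, rose 6.32-fold, from 15.3 ± 1.48 to 96.7 ± 5.57 CPM (adjusted p = 7.87e-07). The drug's target CDK4 fell 1.45-fold (adjusted p = 0.00707) and RB1, the substrate of the kinase, fell 1.44-fold (adjusted p = 0.00034).

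Of 157 repair genes, 12 rose and 105 fell under palbociclib (12 and 106 adjusted over the list alone), with a median log2 fold change of -0.60, and 66.9% fell against 27.3% of other genes. Mismatch repair (2 higher and 7 lower of 9), homologous recombination (0 and 26 of 33) and the Fanconi anaemia pathway (0 and 13 of 17) were called lower, as were base excision repair (3 and 17 of 23), replicative polymerases (0 and 11 of 14) and the damage checkpoint (0 and 11 of 19). Adjusted p values were 0.00158, 5.76e-07, 6.25e-05, 0.0013, 2.29e-05 and 0.00104, and each had adjusted p = 0.328 with an estimated correlation. PCNA, the sliding clamp of replication and repair, fell 4.46-fold, from 292 ± 15.1 to 65.3 ± 16.1 CPM, and the mismatch sensor gene MSH6 fell 2.17-fold. BRIP1 and FANCG fell by 2.13 and 2.03 on the log2 scale, the primase gene PRIM1 by 2.79, and the checkpoint gene H2AFX, which encodes the histone phosphorylated at breaks, by 2.15. The DNA glycosylase gene MBD4 rose 1.81-fold.

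End joining (1 higher and 6 lower of 14, adjusted p = 0.0899), nucleotide excision repair (4 and 11 of 24, adjusted p = 0.115) and low-fidelity polymerases (2 and 6 of 12, adjusted p = 0.203) were not called by camera under palbociclib, while fry called each lower (adjusted p = 0.000429, 0.000998 and 0.000406). Members that fell included XRCC5 (Ku80) at -1.08, the damage sensor DDB2 at -1.07 ± 0.088 and POLH at -0.53.

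Replication licensing (0 higher and 26 lower of 27, median -1.80), G2/M (0 and 33 of 33, median -1.98) and nucleotide supply (1 and 11 of 12, median -1.26) were called lower under palbociclib. These calls had adjusted p values of 2.08e-11, 1.85e-13 and 5.77e-05, each with adjusted p = 0.328 with an estimated correlation. MCM5 and MCM6, subunits of the replicative helicase, each fell 4.45-fold, and TYMS of thymidylate synthesis fell 5.46-fold. The E2F and RB list fell with 4 higher and 13 lower of 23, at adjusted p = 0.0224 and adjusted p = 0.412 with an estimated correlation. In it CDK2 and E2F8 fell 3.55-fold and 9.19-fold, while CCND2 rose 70.9-fold to 353 ± 22.4 CPM. Of the p53 targets 14 rose and 14 fell (adjusted p = 0.559), with CDKN1A 2.69-fold and GDF15 5.99-fold higher.

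Stress, lysosome and sterol genes changed under palbociclib too, in lists with adjusted p = 0.328 with an estimated correlation. Of 25 genes of the ATF4 list 18 rose and 2 fell, among them ASNS, CHAC1 and ATF3 at 1.39, 3.13 and 2.28, and DDIT3, a stress-induced factor, rose 3.90-fold (adjusted p = 6.51e-05). Lysosome and autophagy had 24 higher, such as the calcium channel MCOLN1 (2.86-fold), and 1 lower (GUSB) of 30, and cholesterol synthesis had 1 higher and 15 lower of 23, with ACAT2 at -2.44. The 12q13-15 amplicon list had 3 higher and 15 lower of 26, with HMGA2 at -1.51 ± 0.23 and MDM2 at -0.55 ± 0.16 (adjusted p = 0.0105). The lists had adjusted p values of 5.76e-07, 2.25e-06, 4.97e-05 and 0.0114, each with adjusted p = 0.328 with an estimated correlation. ER chaperones had 11 higher and 7 lower of 27 (adjusted p = 0.548), with HERPUD1 2.21-fold higher. Mitochondrially encoded genes rose (12 of 12, adjusted p = 6.32e-08, and adjusted p = 0.328 with an estimated correlation) and ribosomal protein genes fell (1 higher and 49 lower of 76, adjusted p = 5e-06, and adjusted p = 0.594 with an estimated correlation). Replication-dependent histones had 13 higher, such as HIST1H2AC (4.94-fold), and 3 lower of 25, at adjusted p = 0.0145 and adjusted p = 0.461 with an estimated correlation, with list medians of 1.22 and 0.64 in the libraries.

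Interferon-stimulated genes rose under palbociclib (18 higher and 2 lower of 32, 21 and 3 adjusted over the list alone), at adjusted p = 0.0143 and adjusted p = 0.655 with an estimated correlation, with list medians of 0.46 and 0.87 in replicates 1 and 2. IFI27 and the virion tether BST2 rose 8.15-fold and 54.9-fold, while OAS3 fell 2.57-fold. Glycolysis and hypoxia genes had 12 and 7 of 29 (adjusted p = 0.205, and 0.00648 with the date block), with NDRG1 3.29-fold higher and the glycolytic mutase PGAM1 1.90-fold lower. Secreted inflammatory factors had 8 and 3 of 24 (adjusted p = 0.515), with ICAM1 7.47-fold higher, and matrix genes 14 and 7 of 31 (adjusted p = 0.548), with the collagen gene COL6A1 2.34-fold higher and THBS1 3.60-fold lower. Adipocyte genes had 5 and 3 of 17 (adjusted p = 0.548), efflux genes 9 and 7 of 23 (10 and 7 adjusted over the list alone, adjusted p = 0.858), N-linked glycosylation 11 and 8 of 33 (adjusted p = 0.858) and mTOR regulators 14 and 4 of 37 (adjusted p = 0.199). Among these, the transporter gene ABCG2 fell 3.18-fold, and SESN3 and DDIT4, inhibitors of mTOR complex 1, rose 32.7-fold and 10.9-fold.

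Among the largest changes under palbociclib, EPHA3, FAM83H, LRP3, TP53I11 and MEG3 had no count in parental and were at least 81.3-, 74.2-, 69.2-, 68.9- and 66.9-fold higher. FAM83H differed between the 2 libraries, at 11.6 CPM with an SE of 1.44 on the log2 scale, as did the matrix protein gene MGP, at 54.5 ± 60.2 CPM and a ratio of 2260 (95% interval 626 to 18700). CYP24A1, the vitamin D 24-hydroxylase, fell 39.8-fold from 1273 ± 74.5 to 31.9 ± 19.6 CPM. HBD, LYPD1, LHX1, FAM111B and MAL fell between 16.0-fold and 64.3-fold.

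In all, 9667 genes changed under palbociclib, 5093 higher and 4574 lower. Calls were 65.6% higher with library totals and 63.4% with upper quartile factors, against 52.7%, the median of all genes stood at 0.20 and 0.18 against 0.039, and repair genes had a median of -0.43 with totals. The date block left 1253 genes and 15 repair genes.

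The comparison of tunicamycin with parental asked the same of long exposure to an inhibitor of N-linked glycosylation. DPAGT1, which encodes the enzyme that tunicamycin inhibits, rose 2.90-fold from 49.0 ± 2.21 CPM (SD, n = 4, against n = 2 under the drug), a log2 fold change of 1.53 ± 0.10 (SE, adjusted p = 2.58e-06). It lay in a run of 130 neighbouring genes on chromosome 11 with a median of 0.90. HSPA5, the main ER chaperone, rose 1.44-fold (adjusted p = 0.00564), and DDIT3 rose 2.34-fold (adjusted p = 0.00181). CDKN1A rose 4.10-fold, to 258 CPM (adjusted p = 4.4e-07).

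ER chaperones had 13 higher and 2 lower of 27 under tunicamycin and were not called as a list (adjusted p = 0.167). HYOU1 and SYVN1, an ER chaperone and an ER ubiquitin ligase, rose 1.98-fold and 1.90-fold, while the coat protein gene SEC24D fell 2.17-fold. N-linked glycosylation had 11 higher and 8 lower of 33 (12 and 8 adjusted over the list alone) at adjusted p = 0.987. Members with lower counts were ALG14 (2.62-fold), DDOST of the oligosaccharyltransferase (1.78-fold) and the lipid transporter MFSD2A (5.75-fold). The ATF4 list had 13 higher, such as CEBPB and SLC3A2 (2.54-fold and 2.56-fold), and 3 lower of 25 (14 and 5 adjusted over the list alone). It was called at adjusted p = 0.0353, lost with the date block (adjusted p = 0.186) and adjusted p = 0.715 with an estimated correlation. Of the p53 targets 20 rose and 2 fell of 34, with EDA2R and DDB2 2.84-fold and 2.50-fold higher, at adjusted p = 1.2e-07 and adjusted p = 0.715 with an estimated correlation. List medians in tunicamycin replicates 1 and 2 were 0.677 and 0.383 for the p53 list and 0.546 and 0.294 for the ATF4 list.

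Of 157 repair genes, 26 rose and 58 fell under tunicamycin (26 and 59 adjusted over the list alone), with a median log2 fold change of -0.21, and 36.9% fell against 22.5% of other genes. None of the 9 repair lists was called by camera, and the lowest adjusted p was 0.109, for base excision repair (1 higher and 10 lower of 23). Fry called base excision repair, end joining and low-fidelity polymerases lower (adjusted p = 0.0317, 0.0442 and 0.00273) and nucleotide excision repair higher (adjusted p = 0.00273). RAD54L, a recombination motor protein, fell 4.42-fold, from 49.5 ± 2.15 to 11.2 ± 4.79 CPM, DNA ligase LIG1 fell 2.73-fold, and the polymerase genes POLA1 and POLD1 fell 3.45-fold and 3.57-fold. Higher members were the checkpoint kinase ATM (2.35-fold, from 79.2 ± 4.79 to 186 ± 7.07 CPM), FANCF (2.01-fold), CDK7 (1.96-fold) and DDB2. ATM lay in the same chromosome 11 run as DPAGT1, and RAD54L, LIG1 and POLA1 lay in runs with lower medians on chromosomes 1, 19 and X.

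The other repair lists under tunicamycin were mismatch repair (1 higher and 2 lower of 9, adjusted p = 0.389), homologous recombination (5 and 12 of 33, adjusted p = 0.208) and the Fanconi anaemia pathway (2 and 7 of 17, 2 and 8 adjusted over the list alone, adjusted p = 0.144). End joining had 3 higher and 6 lower of 14 (adjusted p = 0.542), nucleotide excision repair 10 and 3 of 24 (adjusted p = 0.208) and low-fidelity polymerases 2 and 5 of 12 (adjusted p = 0.52). Replicative polymerases had 2 higher and 6 lower of 14 (adjusted p = 0.213) and the damage checkpoint 2 and 10 of 19 (adjusted p = 0.29).

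Replication licensing (0 higher and 15 lower of 27, 0 and 18 adjusted over the list alone) and G2/M genes (0 and 25 of 33, 0 and 28) were called lower under tunicamycin at adjusted p = 0.000957 and 8.16e-05. Both had adjusted p = 0.715 with an estimated correlation, and fry gave adjusted p = 0.056 and 0.0558. The libraries stood apart, with list medians of -1.21 and -0.42 for licensing and -1.47 and -0.73 for G2/M in replicates 1 and 2. CDCA8 and CENPE fell 4.56-fold and 2.96-fold and RPA2 2.52-fold, the last inside a chromosome 1 run with lower medians. Nucleotide supply had 0 higher and 6 lower of 12 (0 and 7 adjusted over the list alone, adjusted p = 0.0606), and the E2F and RB list 3 and 13 of 23 (adjusted p = 0.233), with CDKN2C, in the same run, 5.09-fold lower and CCND2 29.1-fold higher at 145 ± 38.6 CPM. Cholesterol synthesis rose (19 higher and 3 lower of 23), with SQLE and DHCR7 2.39-fold and 2.26-fold higher, and glycolysis and hypoxia fell (2 and 19 of 29, 2 and 20 adjusted over the list alone), with SLC2A1 at -1.74. Their adjusted p values were 8.16e-05 and 0.000141, each with adjusted p = 0.715 with an estimated correlation. Ribosomal protein genes rose (28 higher and 3 lower of 76, 28 and 2 adjusted over the list alone, adjusted p = 0.00793), with adjusted p = 0.715 with an estimated correlation, 0.0692 by fry and list medians of 0.057 and 0.37 in replicates 1 and 2. MTOR fell 1.85-fold (adjusted p = 0.000133), inside a run of 402 genes on chromosome 1 with a median of -0.87, and its list had 12 higher and 10 lower of 37 (13 and 10 adjusted over the list alone, adjusted p = 0.603).

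Interferon-stimulated genes (20 higher and 2 lower of 32, 21 and 2 adjusted over the list alone) and secreted inflammatory factors (17 and 5 of 24, 18 and 5) rose under tunicamycin, and matrix genes fell (5 and 13 of 31). Adjusted p values were 0.000104, 0.00531 and 0.00531, each with adjusted p = 0.715 with an estimated correlation, and the inflammatory list had 0.0549 with the date block. The matrix call rested on tunicamycin replicate 2, with a list median of -0.96, against -0.10 in replicate 1 and -0.12 in parental replicate 3, and the interferon list had medians of 1.40 and 0.48 in replicates 1 and 2. OAS1 and the RNA sensor DDX58 rose 14.6-fold and 2.70-fold, TNFRSF11B (osteoprotegerin) 6.37-fold, and the cytokine IL11 fell 13.5-fold. THBS1 and the proteoglycan gene VCAN fell 8.39-fold and 5.59-fold. Lysosome genes had 13 and 5 of 30 (13 and 6 adjusted over the list alone, adjusted p = 0.144), with the autophagy receptor SQSTM1 4.15-fold higher, and the 12q13-15 amplicon 4 and 8 of 26 (adjusted p = 0.367). Adipocyte genes had 3 and 4 of 17 (adjusted p = 0.987), with a median of -0.088, a mean of 0.23, a test direction of lower and the lipase gene LPL 23.6-fold higher. Efflux genes had 7 and 3 of 23 (adjusted p = 0.34), with the pump gene ABCB1 2.56-fold higher, mitochondrially encoded genes 4 and 0 of 12 (adjusted p = 0.358) and histones 4 and 8 of 25 (adjusted p = 0.542).

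Among the largest changes under tunicamycin, HCN4 and PCDHAC1 had no parental count and were at least 39.3- and 34.2-fold higher. The acute phase gene SAA1 and the protease gene MMP9 had 3 and 1 parental counts, with ratios of 852 (95% interval 292 to 4130) and 905 (162 to 35800). PAGE1 and HBD had no count under tunicamycin and were at least 71.6- and 37.5-fold lower. MAGEC2, FGFR2, COL1A2 and HOOK1 fell 125-, 115-, 48.9- and 47.2-fold.

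In all, 7788 genes changed under tunicamycin, 4052 higher and 3736 lower. With library totals 62.1% of calls were higher against 52.0%, the median of all genes stood at 0.12 against 0.018, and repair genes had a median of -0.11. The date block left 834 genes and 7 repair genes, and without tunicamycin replicate 1 the changed repair genes numbered 53, 23 higher and 30 lower, instead of 84.

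**Figure D2:**
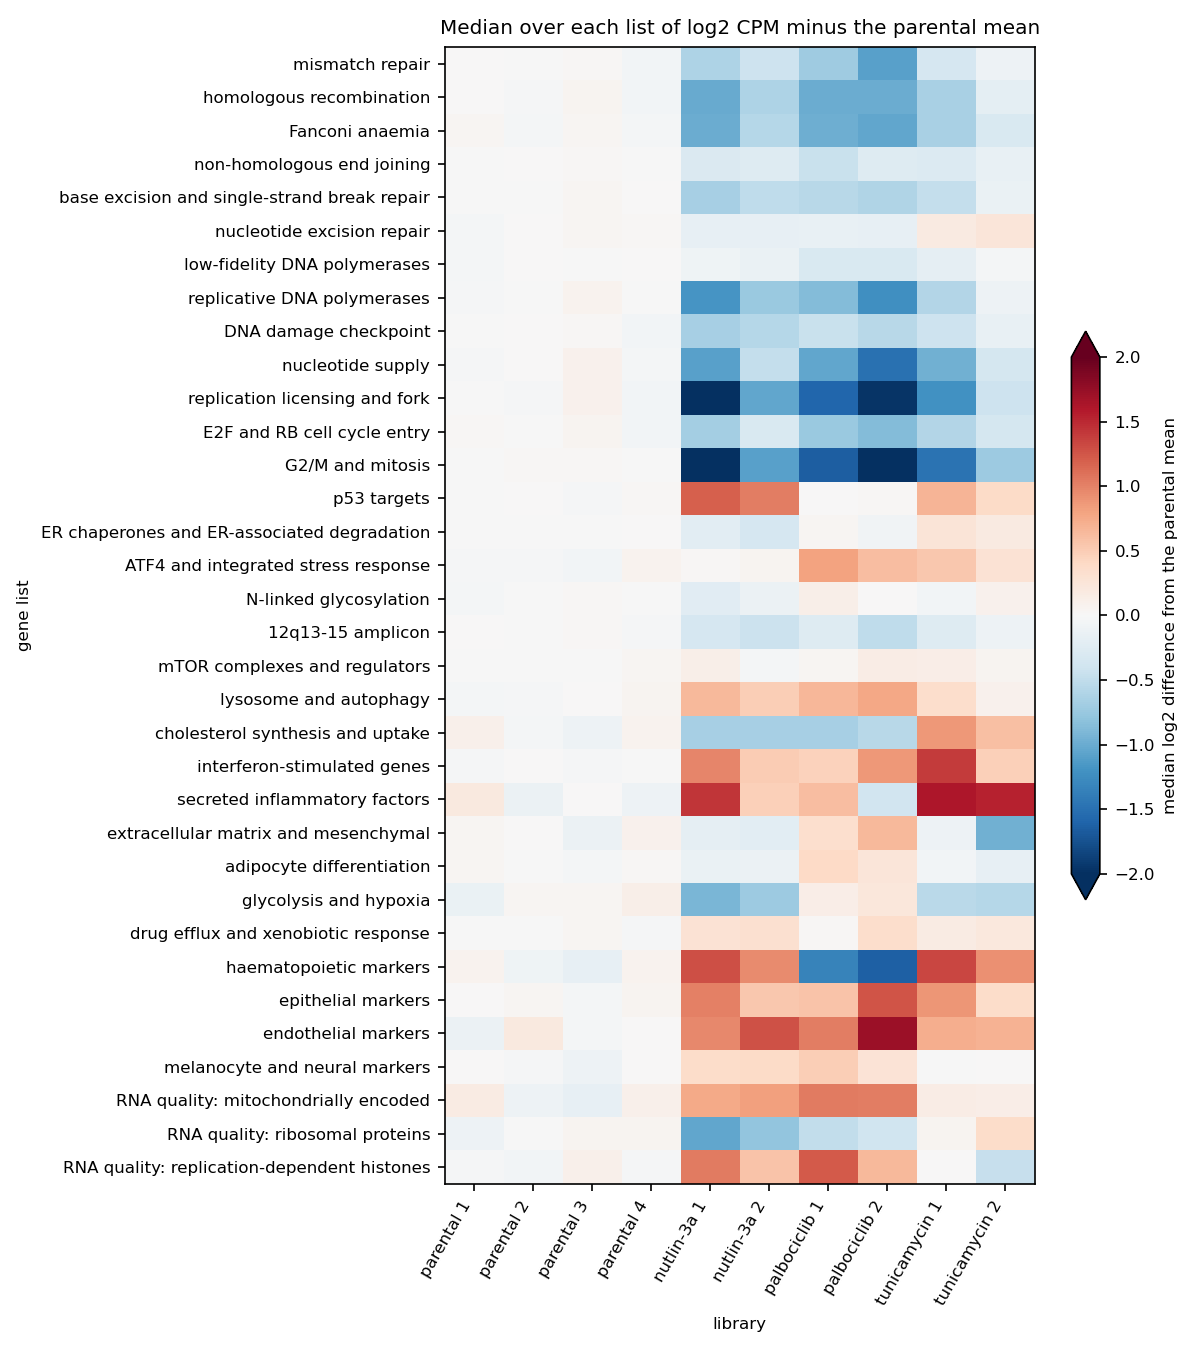
Median over the genes of each of 34 lists of log2 CPM minus the parental mean, for each of the 10 libraries, as colour. Columns are libraries and colours end at -2 and 2; G2/M and replication licensing were lower in every drug library, and the p53 list was highest under nutlin-3a, with a fitted median of 1.11.

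Markers of other cell types were measured beside these groups. Haematopoietic markers had 3 higher and 1 lower of 5 under nutlin-3a, 2 and 3 under palbociclib and 2 and 1 under tunicamycin (adjusted p = 0.297, 0.428 and 0.45). Under palbociclib their median was -1.55 and their mean 0.45. Epithelial markers had 5 and 1, 4 and 2 (5 and 2 adjusted over the list alone) and 3 and 1 of 8 in the same order (adjusted p = 0.827, 0.519 and 0.45), and endothelial markers 4 and 1 (4 and 2 adjusted over the list alone), 4 and 0, and 3 and 1 of 7 (adjusted p = 0.297, 0.121 and 0.294). With the date block, endothelial markers were called higher under palbociclib (adjusted p = 0.0277). Melanocyte and neural markers had 3 and 1, 3 and 0, and 1 and 0 of 8 (0 and 0 adjusted over the list alone under tunicamycin), at adjusted p = 0.555, 0.205 and 0.983. With genes absent from parental at their bound, the epithelial medians were 0.37, 1.31 and 0.62 instead of 0.96, 1.31 and 0.74.

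The mean of the 3 drugs against parental asked which genes differed on average over the drugs, which does not show a change under each of them. On average G2/M genes were lower and p53 targets higher (adjusted p = 0.361 with an estimated correlation for each list), although the p53 list was not called under palbociclib. HLA-DPA1, which encodes an MHC class II chain, had 8.95 ± 3.89 CPM in the drugs (SD, n = 6) against 2 parental counts (n = 4), a ratio of 371 (95% interval 103 to 3070). TP53I11 was at least 38.1-fold higher, CPXM2 and EYA2 had ratios of 1200 (215 to 47200) and 530 (95.1 to 20900), and HBD, PAGE1, MAGEA12 and LYPD1 fell between 20.7-fold and 138-fold. In all 9046 genes changed, 4472 higher and 4574 lower. Calls were 65.4% higher with library totals and 60.2% with upper quartile factors, against 49.4%, and the median of all genes stood at 0.16 and 0.11 against 0.015. With the date block 148 genes passed.

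Of 157 repair genes, 15 rose and 102 fell in the mean of the drugs (18 and 105 adjusted over the list alone). Called lower were homologous recombination (2 higher, 27 lower, 2 and 28 adjusted over the list alone), mismatch repair (1 and 7, 2 and 7), Fanconi anaemia (1 and 15), base excision (1 and 15, 2 and 15), replicative polymerases (1 and 12) and the checkpoint (1 and 12). Adjusted p values were 8.55e-07, 0.00873, 3.92e-05, 0.000268, 1.44e-05 and 0.000408, each with adjusted p = 0.361 with an estimated correlation. G2/M (0 higher, 33 lower), licensing (0 and 27) and nucleotide supply (1 and 11) fell, and p53 targets (25 and 1) and lysosome genes (23 and 1) rose. Their adjusted p values were 3.74e-17, 2.92e-14, 9.58e-05, 7.44e-10 and 2.45e-06, each with adjusted p = 0.361 with an estimated correlation. The 12q13-15 amplicon (5 and 16 of 26) and glycolysis (2 and 17) fell and mitochondrially encoded genes rose (12 of 12), at adjusted p = 0.0229, 0.000241 and 8.55e-07, each also with adjusted p = 0.361 with an estimated correlation. Interferon-stimulated genes (24 and 1 of 32), secreted inflammatory factors (13 and 3 of 24) and the ATF4 list (13 and 4 of 25, 15 and 4 adjusted over the list alone) rose at adjusted p = 1.11e-05, 0.0102 and 0.0052, with adjusted p = 0.428, 0.485 and 0.364 with an estimated correlation. The E2F and RB list (4 and 13, 6 and 14 adjusted over the list alone), cholesterol synthesis (2 and 9) and ribosomal protein genes (0 and 51, 0 and 52) fell at adjusted p = 0.0258, 0.0499 and 1.86e-06, with adjusted p = 0.415, 0.59 and 0.546 with an estimated correlation. Cholesterol synthesis was not called with RLE factors or library totals (adjusted p = 0.0516 and 0.0787). With the date block the inflammatory and ribosomal lists were lost (adjusted p = 0.0777 for each), and matrix genes were called lower and endothelial markers higher (adjusted p = 0.0038 and 0.0325).

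The same 43 repair genes changed alike under all 3 drugs, 42 lower and KIAA1530 (UVSSA) higher. Many repair genes were lower under each drug (99, 105 and 58 of 157), and the number that independent lists would share was not computed for them. The 43 alone therefore do not show a common response particular to repair genes. POLD1 had log2 fold changes of -1.36, -1.23 and -1.84 under nutlin-3a, palbociclib and tunicamycin, POLE -1.40, -1.51 and -1.13, the repair scaffold XRCC1 -0.97, -0.88 and -0.92, and RAD54L -1.44, -1.72 and -2.14. FANCC, DNA2, MUTYH, RNF168, POLA1, TIMELESS and LIG1 also fell in each comparison, and KIAA1530 rose by 0.90, 0.44 and 0.53. The blocked fit by date called 4, 15 and 7 repair genes under the 3 drugs, so at most 4 were left alike in all 3, and KIAA1530 was called under none.

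**Figure D3:**
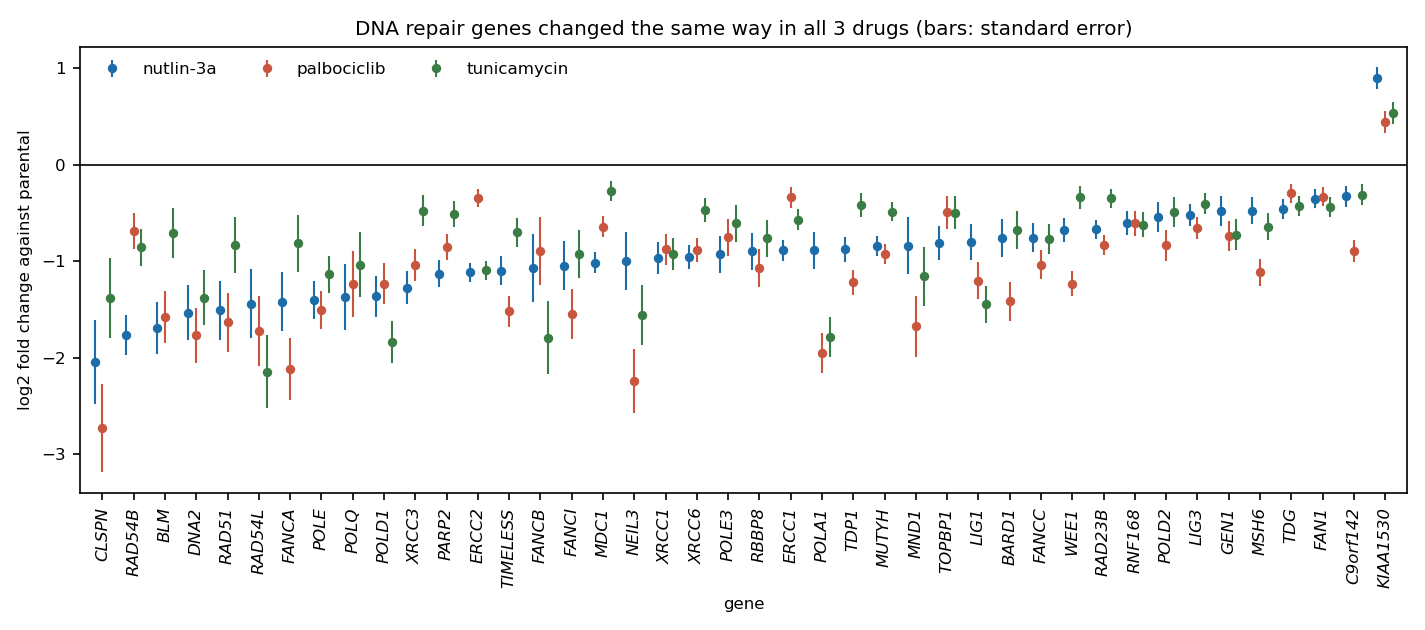
Log2 fold change against parental of 42 of the 43 repair genes that changed alike under the 3 drugs, with 1 point per drug and gene and bars of 1 SE. Only KIAA1530 stands above 0, and POLD1 lies at -1.36, -1.23 and -1.84.

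Over all genes, 2093 changed in the same direction under the 3 drugs, 1081 higher and 1012 lower, where independent lists would share 355.9 and 285.7. The directions depended on the scale, with 1590 higher and 579 lower on library totals and 1341 and 726 with upper quartile factors. With the date block the number was 97. All 3 comparisons used the same parental libraries, and edgeR called 0 genes alike in simulated unchanged groups against them. The simulation held no effect of the title date and gave drug and parental libraries the same spread. It therefore covers only the sharing of controls, not a difference that came with the dates. The log2 fold changes of nutlin-3a and palbociclib correlated across genes at r = 0.716, against 0.335 in the simulation and 0.682 with the controls split into separate pairs. For nutlin-3a and tunicamycin r was 0.414 (0.33 simulated, 0.394 split) and for palbociclib and tunicamycin 0.375 (0.335 and 0.361). The covariances were 1.33, 0.686 and 0.646, against 0.0221, 0.0221 and 0.0223 in the simulation, and the differences were 1.31, 0.664 and 0.624.

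In pairs, nutlin-3a and palbociclib shared 2860 higher and 2827 lower genes, with 633 opposite, where independent lists share 1452 and 1264. Nutlin-3a and tunicamycin shared 1638 and 1554, with 1637 opposite, against 1155 and 1032. Palbociclib and tunicamycin shared 1624 and 1538, with 1678 opposite, against 1249 and 1034. With split controls the shared numbers were 2064 and 2152, 1084 and 1014, and 1043 and 1039, against 966.2 and 855, 710.8 and 659.3, and 766.1 and 677.4 for independent lists.

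The direct comparison of nutlin-3a with palbociclib asked where the responses differed. The p53 list was higher under nutlin-3a (24 higher, 1 lower of 34, 26 and 1 adjusted over the list alone, median 0.96), and the ATF4 list (0 and 18 of 25, median -1.03) and glycolysis and hypoxia genes (0 and 23 of 29, 0 and 24 adjusted over the list alone, median -0.75) were lower. They had adjusted p values of 2.52e-19, 7.19e-13 and 1.71e-14, with adjusted p = 0.209, 0.209 and 0.221 with an estimated correlation. Ribosomal protein genes were lower too (2 and 38 of 76, 3 and 41 adjusted over the list alone, adjusted p = 4.13e-07, and adjusted p = 0.838 with an estimated correlation). PLCH2 was 279-fold and the inositol phosphatase gene INPP5D 166-fold higher under nutlin-3a, and the hypoxia-induced carbonic anhydrase CA9 had 28.1 ± 0.396 CPM under palbociclib against 1 count under nutlin-3a, a ratio of 1200 (95% interval 216 to 47500). Of 157 repair genes, 35 were higher and 17 lower under nutlin-3a, and no repair list was called by camera, while fry called mismatch repair and low-fidelity polymerases higher (adjusted p = 0.0445 and 0.00031). Genes changed numbered 6478, 3231 higher and 3247 lower, 2736 with the date block and 3860 when only these libraries were fitted.

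Nutlin-3a against tunicamycin asked the same of that pair. Cholesterol synthesis was lower under nutlin-3a (1 higher, 18 lower of 23, median -1.33), and so were ribosomal protein genes (0 and 71 of 76), homologous recombination (2 and 17 of 33) and the ATF4 list (6 and 13 of 25, 6 and 15 adjusted over the list alone), while p53 targets (16 and 7 of 34) and mitochondrially encoded genes (10 and 0 of 12, 11 and 0) were higher. Adjusted p values were 2.54e-11, 2.27e-24, 0.0324, 0.0292, 0.0309 and 0.0324, each with adjusted p = 0.86 with an estimated correlation. Of 157 repair genes 19 were higher and 70 lower under nutlin-3a (20 and 71 adjusted over the list alone). IGFBP5, an insulin-like growth factor binding protein, stood at 194 ± 26.2 CPM under nutlin-3a and 0.139 ± 0.124 under tunicamycin, while WNT7A and LHX1 had no count under nutlin-3a and were at least 145- and 88.2-fold lower. Genes changed numbered 8884, 4458 higher and 4426 lower, and 5844 with the date block.

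Palbociclib against tunicamycin asked it of the last pair. Homologous recombination (1 higher, 20 lower of 33), nucleotide excision repair (2 and 12 of 24) and replicative polymerases (1 and 7 of 14) were lower under palbociclib, at adjusted p = 0.00329, 0.0185 and 0.0185, each with adjusted p = 0.659 with an estimated correlation. Replication licensing (2 and 17 of 27) and G2/M (0 and 18 of 33) were lower at adjusted p = 0.00289 and 0.00166, each with adjusted p = 0.687 with an estimated correlation. The p53 list (9 and 22 of 34) and cholesterol synthesis (1 and 21 of 23) were lower, and glycolysis and hypoxia genes (17 and 3 of 29), the ATF4 list (15 and 3 of 25, 16 and 4 adjusted over the list alone), lysosome genes (18 and 5 of 30, 18 and 6) and matrix genes (13 and 3 of 31) were higher. Their adjusted p values were 0.000758, 9.92e-11, 9.64e-05, 0.0284, 0.0178 and 0.00596, each with adjusted p = 0.659 with an estimated correlation. Mitochondrially encoded genes (11 and 0 of 12, 12 and 0 adjusted over the list alone) and histones (13 and 0 of 25) were higher and ribosomal protein genes (3 and 56 of 76) lower, at adjusted p = 0.000758, 0.016 and 2.33e-09, also each with adjusted p = 0.659 with an estimated correlation. CA9 had no count under tunicamycin and was at least 179-fold higher under palbociclib, and TIE1, an endothelial receptor gene, was 134-fold lower, at 0.534 ± 0.187 against 72.7 ± 23.5 CPM. Of 157 repair genes 14 were higher and 81 lower. Genes changed numbered 9576, 4888 higher and 4688 lower, and the median of all genes stood at 0.11 with upper quartile factors against 0.018.

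Neighbouring genes moved together along parts of several chromosomes, in a scan chosen after seeing the data. Under tunicamycin, 12 runs held 1150 of 9230 ordered genes (12.5%), and 83.9% of those changed. The longest spanned 402 genes of chromosome 1 from MIB2 to BCL10, with a median of -0.87 and a median of -0.79 in the library nearer to 0, and 94.8% of its genes lay on that side. A further 77 genes from ALG14 to TBX15 had a median of -1, 98 genes of chromosome X from HCCS to HUWE1 -0.90, and 130 genes of chromosome 11 from PRCP to PUS3 0.90. Nutlin-3a had 4 runs with 268 genes, the longest of 150 genes on chromosome 7 from EIF4H to ATP6V1F, with a median of 0.76. Palbociclib had 2 runs with 58 genes, both lower and on chromosome 11, and CHEK1, a checkpoint kinase gene in the second, fell by 1.67.

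**Figure D4:**
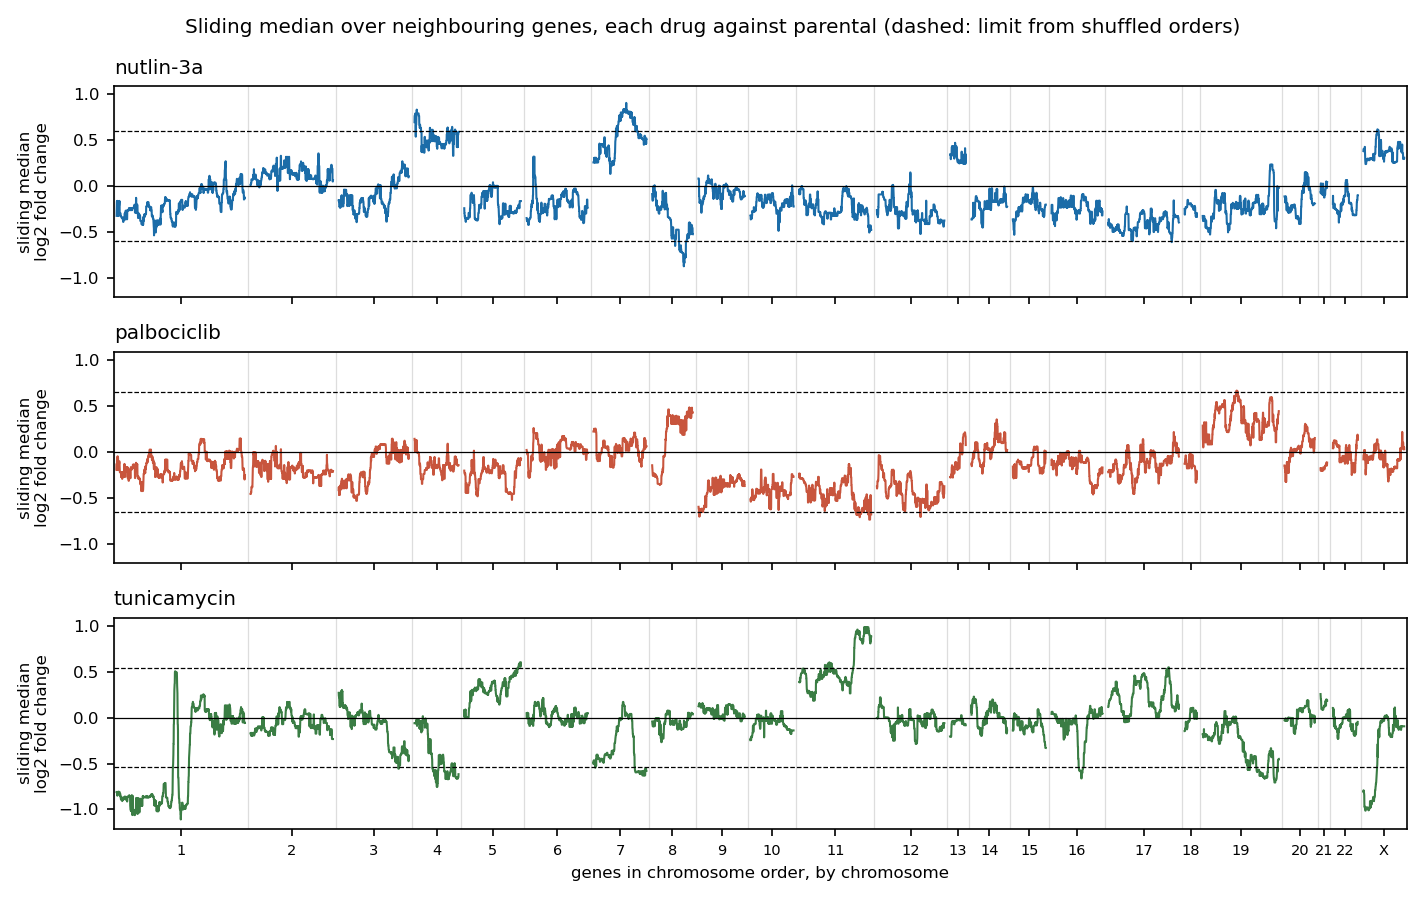
Sliding median of log2 fold change over 41 neighbouring genes, along the chromosomes, with 1 panel per drug. Dashed lines mark the most extreme medians of shuffled orders, 0.603, 0.657 and 0.537 for nutlin-3a, palbociclib and tunicamycin. The long stretch of chromosome 1 below the line under tunicamycin had a median of -0.87.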

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

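Each value below was picked out by a rule fixed beforehand unless stated, and no test of a cause was made for it. A Dixon test singled out 1 parental library in 16 of the 290 groups of gene values tested (5.52%), near the rate of 1 in 20 that chance alone gives.

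In parental replicate 1, CDC20 stood at 371 CPM (412 to 417 in the other 3 parental libraries), CEBPB at 46.1 CPM (40.5 to 41.4), HIST1H2BD at 2.55 CPM (3.29 to 3.31) and KRT18 at 356 CPM (408 to 418). In the same library MAGEA12 stood at 2.17 CPM (5.95 to 6.63), RRAGD at 7.56 CPM (2.5 to 2.68), SC5DL at 36.3 CPM (30.9 to 31.2) and TNFRSF11B at 8.41 CPM (6.37 to 6.53).

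In parental replicate 2, IFIH1 stood at 19.9 CPM (18.2 to 18.4) and MLH3 at 16.4 CPM (14 to 14.2). In parental replicate 3, ALG14 stood at 12.6 CPM (10.6 to 10.7), CDKN1A at 55.7 CPM (64.5 to 65.8), FASN at 272 CPM (331 to 335), ORC6 at 38.2 CPM (34.7 to 35.2) and VCAN at 136 CPM (190 to 200). In parental replicate 4, FDPS stood at 105 CPM (94.5 to 95.9).

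Reads in no annotated gene made up 9.39% of all reads under nutlin-3a, 9.56% under palbociclib and 8.24% under tunicamycin, against 7.316 to 7.83% in parental libraries. Reads that fitted more than 1 gene made up 2.07% under tunicamycin, against 1.686 to 1.747% in parental. Between the 6 drug and 4 parental libraries, an exact two-sided permutation test over 210 splits gave p = 0.00952 for reads in no annotated gene (9.06 against 7.50%) and p = 0.467 for reads fitting more than 1 gene (1.81 against 1.72%). For measures that the rule had not picked, the same exact test gave p = 0.019 for the number of genes with a count (23301 against 21525), p = 0.0143 for mitochondrially encoded genes (3.13 against 1.80%) and p = 0.681 for ribosomal protein genes (3.30 against 3.57%). The permutations treat the libraries as independent, although both libraries of a drug may be technical replicates, and they do not separate drug from title date.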

How the results depend on the processing

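With the title date as a block, changed genes numbered 957 for nutlin-3a, 1253 for palbociclib, 834 for tunicamycin and 148 for the mean of the drugs, 2736 for nutlin-3a against palbociclib and 5844 for nutlin-3a against tunicamycin. Changed repair genes then numbered 4, 15 and 7 for the 3 drugs, and 97 genes changed alike in all 3. Against parental, the block changed no list call other than those given with the lists, and lists of the drug pairs were not tested with it. With the palbociclib dates exchanged the numbers were 3920, 4117, 3032, 1768, 5515, 8167 and 8822 for the 7 comparisons, 61, 65 and 24 repair genes, and 420 genes alike.

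With a minimum of 1 in absolute log2 fold change, changed genes numbered 3627 (2381 higher, 1246 lower), 4015 (2718, 1297) and 3079 (1823, 1256) for nutlin-3a, palbociclib and tunicamycin and 2563 (1812, 751) for their mean, so that calls leaned higher. They numbered 2510 (1103, 1407) for nutlin-3a against palbociclib, 4225 (2374, 1851) for nutlin-3a against tunicamycin and 4758 (2750, 2008) for palbociclib against tunicamycin. Repair genes then numbered 36, 50 and 18, and 749 genes changed alike in all 3 (593 higher, 156 lower). With only the compared groups fitted, 3860 genes differed between nutlin-3a and palbociclib. Limma-voom with 1 weight per group called 9595 genes for nutlin-3a, 8471 for palbociclib, 6346 for tunicamycin and 9407 for the mean. It called 4760 for nutlin-3a against palbociclib, 7111 for nutlin-3a against tunicamycin and 6831 for palbociclib against tunicamycin.

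Leaving out each library in turn gave 6396 to 9940 genes for nutlin-3a, 7822 to 10582 for palbociclib, 6002 to 8452 for tunicamycin and 7656 to 9672 for the mean. The drug pairs gave 4584 to 7400, 7162 to 9527 and 8442 to 9878. Where 1 library of a drug was left, it was assumed to vary like the other groups. Repair genes numbered 76 to 119 for nutlin-3a (76 without nutlin-3a replicate 1), 97 to 120 for palbociclib and 53 to 90 for tunicamycin (53 without tunicamycin replicate 1), and genes alike in all 3 numbered 1437 to 2611.

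A few fixed genes that were not called changed sign, near 0, and the cause was not tested. Under nutlin-3a, CCND1 had -0.094 with the date block and -0.060 without nutlin-3a replicate 2 (0.081 without replicate 1), and DDIT3 -0.048 with the block and -0.12 without nutlin-3a replicate 1 (0.62 without replicate 2). Under palbociclib, CCND1 had -0.021 without a filter, -0.12 with the block and -0.19 without palbociclib replicate 1 (0.19 without replicate 2). HSPA5 had -0.019, -0.10 and -0.059 in those same 3 settings (0.085 without replicate 2), DPAGT1 -0.13 without palbociclib replicate 1 (0.29 without replicate 2), and MTOR 0.045 with totals, 0.020 with upper quartile factors and 0.0082 without palbociclib replicate 2 (-0.29 without replicate 1). Under tunicamycin, MDM2 had -0.14 with the block, and RB1 0.084 with totals, 0.028 with upper quartile factors, 0.0040 with the CPM filter, 0.016 with the block and 0.069 without tunicamycin replicate 1.

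Of 9687 values of named genes over the settings other than the fold minimum and the exchanged dates, 9303 stayed as called, 361 were no longer called, 3 became called and 20 changed sign. The date block alone accounted for 260 of the 361, and under it 221 of 487 values stayed as called and 6 changed sign. With a correlation estimated from the data, 64 of 136 list results against parental, called or not, became weaker, and no call against parental was kept. With fry, 38 of the 136 became stronger, repair lists and lists outside repair among them, and 3 became weaker.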

Other observations

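In this part, every test was chosen after its result or the pattern was seen, except those of grouping by chance, of repair genes outside the runs, of GC content and of DNA copy number. For grouping by chance, 1 of 100 drawn splits, the real one with 3178 genes, reached that number and the highest other gave 0 in edgeR. Every other split mixed parental and drug libraries on 1 side, which widens the spread and leaves few calls. Libraries of a group may also be technical replicates, so the splits cannot exclude chance differences between cultures. The wording of the GC content test was tidied before its result existed, and the test on the number of reads was rewritten before its ratio was computed.

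A set of 11 genes had at most 3 counts over the 4 parental libraries and at least 1 CPM under each drug, and 0 genes showed the reverse. The MHC class II gene HLA-DPA1 stood at 7.15, 12.6 and 7.09 CPM under nutlin-3a, palbociclib and tunicamycin, the neuronal membrane gene RTN1 at 11.4, 12.2 and 2.44, the neurotrophin receptor NTRK2 at 1.81, 17.5 and 1.69 and the eye development gene EYA2 at 13.2, 1.24 and 4.65. The others were CPXM2, CXCL10, DOK5, HCN4, IL1F8, PDE3B and PNLIPRP3. With libraries thinned to 18814114 counts, 20887 to 21196 genes had a count in parental and 21998 to 24185 in drug libraries.

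DNA repair genes were mostly lower under nutlin-3a and palbociclib, while under tunicamycin 58 of 157 fell and 26 rose (30 and 23 without tunicamycin replicate 1) and camera called no repair list, and a lower expression of repair genes in cells kept under the first pair of drugs is a hypothesis. Under nutlin-3a and palbociclib, 56 repair genes outside the cell cycle list had medians of -0.22 (95% interval -0.41 to -0.15) and -0.34 (-0.48 to -0.14). The fall was thus not confined to genes of the cell cycle list. The 56 genes were not compared with other genes, and some lists outside repair had medians as low under nutlin-3a. ER chaperones stood at -0.35 and the 12q13-15 amplicon at -0.37, while others rose, such as lysosome genes at 0.56. These values therefore cannot decide whether fewer cells in S and G2/M phase were the whole cause. Medians of -0.36 (-0.51 to -0.27) and -0.43 (-0.58 to -0.32) for 157 genes on library totals argued against composition scaling alone. The 56 genes were not tested on library totals, so both explanations acting together stay open. Under tunicamycin these explanations cannot be told apart from an effect on repair genes, with medians of 0.024 (-0.19 to 0.17) outside the cycle list and -0.11 (-0.21 to -0.013) on totals. The 126 genes outside chromosome runs had a median of -0.20 (-0.30 to -0.094). That interval crossed the bound set beforehand, so the test itself stayed undecided. Among the 126 genes 20 rose and 44 fell, against 1 and 8 of the 12 inside runs. Most of the lower repair genes among those ordered thus lay outside the runs. The cell cycle list was extended after the lists had been seen. Protein levels and repair activity were not measured, and a change in growth rate that acts on genes outside the cycle list stays open.

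Runs of neighbouring genes shifted together under tunicamycin and nutlin-3a, and a change in DNA copy number may lie behind the 3 largest tunicamycin runs, with 635 genes, where at least 86.4% of genes lay on the side of the median and genes of higher and lower expression differed by -0.18 to -0.11. Most other runs had differences of about that size or nearer to 0. Examples were 0.085 from ALG14 to TBX15 and -0.094 from HCCS to HUWE1 under tunicamycin, and -0.077 from EIF4H to ATP6V1F under nutlin-3a. The difference was larger, and went against a change in copy number, from IGFBP7 to G3BP2 under nutlin-3a (-0.90, with 76.2% of genes on one side) and from FTH1 to BAD under tunicamycin (-0.44). From RCHY1 to HERC5 under tunicamycin it was -0.37. Runs were picked for an extreme median, and each had at least 76.2% of genes on that side (89.7% from FTH1 to BAD). The share on 1 side therefore does not weigh for a change in copy number. GC content and transcript length were excluded, as 16 of 16 runs kept at least 0.5 of their median after a fit on both. The smallest ratio between library medians was 0.535, from IGFBP7 to G3BP2 under nutlin-3a (1.03 and 0.551). The limit for that ratio was set after the values were seen, and runs were found on both libraries together. Library medians were -0.997 and -0.791 from MIB2 to BCL10, -1.13 and -0.898 from ALG14 to TBX15 and -0.89 and -0.898 from HCCS to HUWE1. They were 0.819 and 0.977 from PRCP to PUS3, all under tunicamycin, and 0.773 and 0.766 from EIF4H to ATP6V1F under nutlin-3a. In these runs the values argued against a single deviating library. For the other runs it was not excluded. The DNA was not measured, and a regional change in chromatin or a different subclone in the culture would look the same.

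Genes silent in parental and on under all 3 drugs might come from a few cells of another type. For HLA-DPA1, with at least 7.09 CPM, blood cells were argued against by CD74, LAPTM5, TYROBP and SPI1, which reached at most 0.349 CPM, under a criterion that replaced an earlier one on 15 markers, undecided at 4 of 15. Other blood markers went both ways, with CD53 from 0.0131 to 10.1 and ITGB2 from 25.2 to 103 CPM under nutlin-3a and PTPRC from 4.90 to 12.1 and LCP1 from 0.501 to 3.29 CPM under tunicamycin, but PTPRC at 1.59 and ITGB2 at 6.66 CPM under palbociclib, CORO1A lower under each drug (6.03 to 2.24, 2.06 and 1.62 CPM) and CD3E, CD3D, CD2 and TYROBP at 0 throughout, and the other 10 genes were not tested for such a source. More reads in drug libraries were excluded, because parental libraries held 2.01 times the counts of the deepest drug pair. Another founder population or stock, another cell line and a response to the drugs were not tested and stay open.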
